A study of Arabidopsis thaliana with 6 samples.

How the data were processed

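Polyadenylated RNA was sequenced from roots of Arabidopsis thaliana seedlings aged 8 days, with strand-specific libraries made by the dUTP method after extraction with an RNeasy kit, per the labels' protocols. The 6 deposited columns fall into 3 groups by title: Col-0 wild type on medium with phosphate (replicates 1 and 2), wild type on phosphate-deficient medium (replicates 3 and 4) and the phl2 mutant on deficient medium (replicates 5 and 6). Each replicate number occurs in 1 group, so the numbers pair no samples. The labels do not say whether replicates came from separate plants or cultures, so p-values measure the spread between these libraries, which may be technical. The mutant with phosphate was not analysed here, so a difference between phl2 and wild type under deficiency cannot be divided into a general difference and one in the response.

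The values are RPKM (reads scaled to the length of the gene and the total of the library), deposited by the authors as 1 table of 33602 genes. The submitters' processing notes name TopHat2, DESeq2 and the build TAIR10, without versions, order or role. The counter, its strand setting and the set of reads that the values are divided by are not given in the sources used here. In genes with 1 annotated transcript, low values times exonic length gave the worth of 1 read in each library, and from it a denominator of 9410000, 9990000, 10030000, 10880000, 12790000 and 11070000 reads for replicates 1 to 6. A value of 1 RPKM in a gene of 1 kb thus rests on 9.4 to 12.8 reads. The exonic lengths came from another release of the annotation than the authors' one, and with them 39.3% to 42.6% of low values fell within 0.1 read of a whole number, so no count test was run. Part of these values would lie that near a whole number by chance. The denominators, read totals and shares given here are therefore approximate. The reads behind the whole table came to between 616039 and 912646 per library, or 5.44% to 9.07% of the denominators.

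The phl2 columns were compared before averaging. Once the worth of 1 read was divided out (a ratio of 1.156 between the columns), 17207 of 21237 genes above 0 in either column, 81.0%, held equal reads in both, within a relative tolerance of 0.001. Replicate 6 was lower in the other 4030 genes and higher in 0. Their chi-square per gene was 0.227, against 1.273 and 1.143 for the wild-type pairs, and no other pair of libraries had equal reads in more than 9.6% of genes. The columns thus differed by less than the sampling noise, and their mean was used as 1 sample. The comparisons had been planned with both columns as replicates. That fit was run as an alternative added after the data were examined.

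Values were analysed as log2(RPKM + 1), with a pseudocount of 1, over the 11463 genes with at least 1 RPKM in 2 or more of the 6 libraries. A log2 change on this scale understates the change of low genes. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to the 5 samples (2 residual degrees of freedom, prior degrees of freedom 6.3), with moderated variances that follow a trend with level. The 3 contrasts were tested two-sided with Benjamini-Hochberg adjustment, and genes with adjusted p under 0.05 were called. The single phl2 sample has no spread of its own and is assumed to vary like the wild-type libraries. Errors of log2 changes are standard errors from limma. Starvation induced or repressed genes were those called in wild type with a change of at least 2-fold.

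Because most genes moved together between libraries, every contrast is also given after each library was rescaled by the median of ratios to the geometric mean over genes, as planned before the data were examined. The factors were 0.98, 0.82, 1.34, 1.21 and 0.77 for replicates 1 to 4 and the phl2 sample. The reference annotation (TAIR10.1, from RefSeq) matched 32827 of the 33602 genes with exons. It supplied names, coordinates and the share of each gene's exons that lies opposite to exons of another gene. All coordinates are on TAIR10.1, 1-based. No coordinates of the authors' build were mixed with them. An alternative added after the data were examined used the 7738 tested genes with no opposite-strand exon, rescaled by their own medians.

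Gene lists of 334 members in 23 groups (2 further members, PHL3 and HSP70-4, were dropped from the lists because the reference gives them another symbol) and the naming rule were fixed before the data were examined. The rule takes PHR1 and its relatives PHL1 to PHL4 first. It then takes up to 8 rises and 8 falls of the largest size among called genes with at least 5 RPKM in the higher group and no overlap between libraries. Last come up to 4 members of each list with the smallest adjusted p, or up to 6 in the phosphate and membrane lipid lists. The 22 lists other than the reference genes were tested with limma's camera (preset correlation 0.01, adjusted over lists within a contrast), with an estimated correlation, and with fry, which asks whether a list's genes move one way without comparing them with other genes. In 20 simulated data sets per comparison with 200 changed genes, the fit of the 11463 genes as deposited recovered 96.2% of genes changed by 1 on the log2 scale and 17.7% of those changed by 0.5 in the contrast of the wild-type groups. In the contrast of phl2 with deficient wild type it recovered 77.3% and 7.8%, with 14.55 false calls per data set. The rescaled fit recovered 84.4% and 7.1% in that contrast. Simulated genes varied independently, without a library-wide shift, and the phl2 sample was given the spread of the fit. The real data may depart from this, so these figures may not hold for them.

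Other alternatives, fixed before the data were examined, were pseudocounts of 0.1 and 5, no filter or a filter at 5 RPKM, quantile normalization, variances without a trend or with robust estimation, fits to the libraries of the compared groups alone, each library left out, stricter thresholds, and other definitions of starvation genes. The smallest number of samples in a group is 1, so splits of the samples were not counted. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 prepared the table and the figures.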

Results

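The data describe roots of Arabidopsis seedlings under phosphate starvation, in wild type and in a mutant of PHL2, a MYB-type transcription factor related to PHR1, the known activator of phosphate starvation genes. The comparisons ask how wild-type roots respond to deficiency and how the roots of phl2 differ from them. There were 2 wild-type libraries with phosphate, 2 without, and 2 phl2 columns without phosphate that shared their reads and were counted as 1 sample. Wild-type values below are mean RPKM ± SD (n = 2) and phl2 values are single. Between 20607 and 21900 genes per column were above 0. The reads behind the table came to 662209 and 616039 with phosphate, 909587 and 912646 in deficient wild type, and 695810 and 665427 in the phl2 columns. As shares of the denominators these were 7.04% and 6.17%, 9.07% and 8.39%, and 5.44% and 6.01%. If the strand opposite to each gene was counted, which is weighed below, most values rest on residual reads of the gene's own transcripts.

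PHL2 itself (AT3G24120, chromosome 3, 8705608 to 8708336) was listed at 1.65 and 2.37 RPKM in the wild-type libraries with phosphate, at 2.14 and 2.24 in those without, and at 1.04 and 0.93 in the phl2 columns. The mutant value was 45.1% of that of deficient wild type, a log2 difference of -0.68 ± 0.22 (adjusted p = 0.055, limma). After rescaling it was -0.25 ± 0.24 and was not called, so a lower PHL2 transcript level beyond the shift of other genes was not shown. Nor is it excluded, since phl2 is 1 sample and the pseudocount understates changes at such low values. In simulated data, the rescaled fit recovered 7.1% of phl2 changes of 0.5. PHR1 (AT4G28610) was at 1.35 ± 0.32 with phosphate, 1.91 ± 0.47 without and 0.95 in phl2. PHL1 (AT5G29000) was at 1.01 ± 0.15, 1.58 ± 0.11 and 0.72. Neither was called in wild type (adjusted p = 0.22 and 0.11) or in phl2 (adjusted p = 0.089 and 0.06). PHL3 (AT4G13640; 0.43 ± 0.15, 0.66 ± 0.07 and 0.13 RPKM) and PHL4 (AT2G20400; 0.80 ± 0.08, 0.63 ± 0.08 and 0.44) were below the level for testing.

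Most genes moved together between the groups. The median tested gene was higher by 0.33 on the log2 scale in deficient than in sufficient wild type, and its log2 change in phl2 against deficient wild type was -0.48. Rescaling brought these medians to 0.01 and -0.01. Changes are given as deposited and then relative to this shift, as rescaled values. Among the reference genes, UBQ10 (a polyubiquitin gene) stood at 28.7 ± 2.39 RPKM with phosphate, 43.5 ± 6.39 without and 22.8 in phl2. Its log2 change was 0.58 in deficiency and -0.90 in phl2 as deposited, and 0.09 and -0.18 after rescaling. ACT2 (an actin gene) changed by 0.11 in deficiency as deposited and by -0.36 after rescaling, and by -0.62 and then 0.06 in phl2. The median change of all 7 reference genes in phl2 was -0.793 as deposited and -0.141 after rescaling. Of 7 reference genes, 3 were called higher in deficiency and 5 lower in phl2 as deposited. After rescaling, 1 was called lower in deficiency and 0 were called in phl2, against 3 and 0 adjusted over the list alone.

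**Figure D1:**
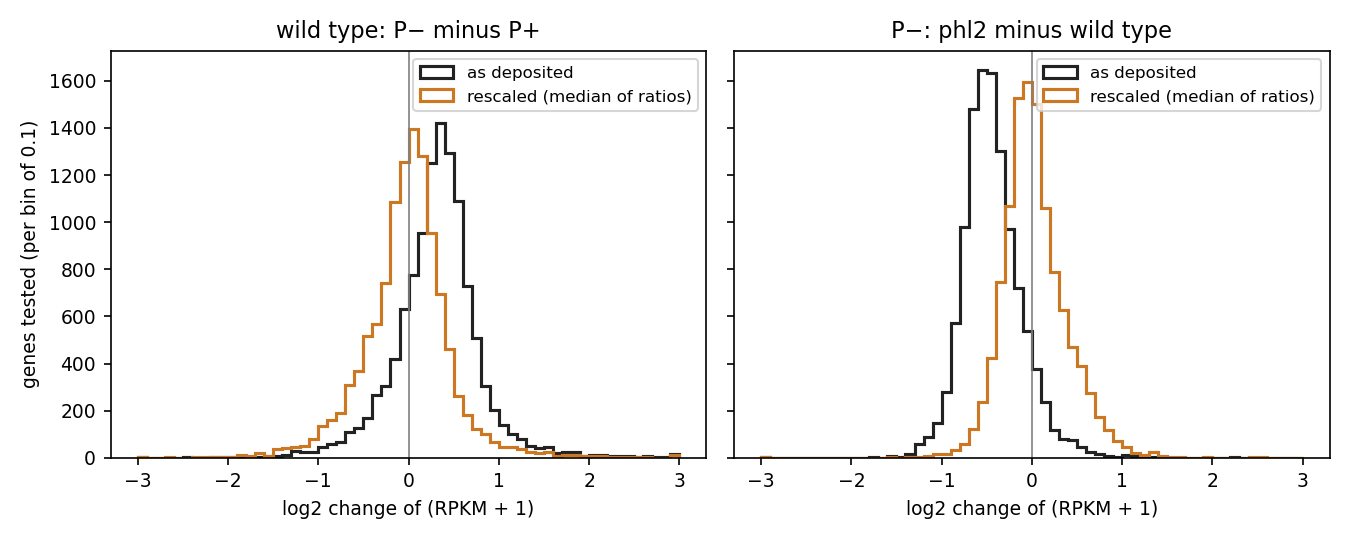
Histograms of the log2 change of (RPKM + 1) over the 11463 tested genes, in bins of 0.1, for deficiency in wild type (left) and phl2 against wild type under deficiency (right). The black outlines (as deposited) have medians of 0.33 and -0.48, the orange outlines (rescaled) 0.01 and -0.01, and changes beyond 3 are drawn at 3.

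Phosphate deficiency in wild type raised most of the measured genes of phosphate sensing, uptake and recycling. SPX1, a sensor that restrains PHR1, went from 0.47 ± 0.02 to 15.0 ± 2.49 RPKM, a log2 change of 3.43 ± 0.16 (adjusted p = 1.6e-05; 3.06 after rescaling). SPX3 went from 0.16 ± 0.23 to 11.6 ± 2.07 RPKM (3.44 ± 0.20). The non-coding RNAs IPS1 and AT4, which bind the microRNA that targets PHO2, rose from 0.10 ± 0.14 to 10.1 ± 2.08 and from 2.07 ± 0.33 to 24.4 ± 1.02 RPKM. PHO2, which encodes a ubiquitin-conjugating enzyme that limits phosphate transport, fell from 5.35 ± 1.04 to 3.29 ± 0.26 (-0.56 ± 0.17, adjusted p = 0.039). Of 12 measured phosphate signalling genes, 9 rose, 1 fell and 2 were not called, with the same counts adjusted over the list alone.

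Of 10 phosphate transport genes, 9 rose and 1 was not called, also adjusted over the list alone. The root uptake transporters PHT1;1 (5.20 ± 1.24 to 27.4 ± 3.13 RPKM), PHT1;2 (3.70 ± 0.96 to 27.7 ± 4.22) and PHT1;4 (0.84 ± 0.07 to 10.6 ± 1.93) changed by 2.2 ± 0.17, 2.62 ± 0.18 and 2.65 ± 0.17. PHT1;1 and PHT1;2 are close copies, and reads may be divided between them. PHO1, which loads phosphate into the xylem, stood at 5.14 ± 0.81 and 6.23 ± 1.06 RPKM (adjusted p = 0.29). Phosphatases and nucleases rose in 12 of 14 cases, and in 13 adjusted over the list alone. PS2, a pyrophosphatase, went from 0.18 ± 0.01 to 17.62 ± 2.63 RPKM (3.98 ± 0.16). PECP1, a phosphocholine phosphatase, was listed at 0 with phosphate and at 14.3 ± 2.21 without. The purple acid phosphatase PAP17 went from 2.91 ± 0.03 to 12.5 ± 2.18 RPKM.

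Membrane lipid remodelling genes, whose products replace phospholipids by galactolipids and sulfolipids, rose in 14 of 17 cases, and in 15 adjusted over the list alone. MGD3, a monogalactosyldiacylglycerol synthase, changed by 2.98 ± 0.16 (0.19 ± 0.10 to 8.37 ± 0.73 RPKM). SQD2, the sulfolipid synthase, changed by 2.51 ± 0.15 (1.11 ± 0.03 to 11.01 ± 1.36), and the phospholipase NPC4 by 2.84 ± 0.16. These 4 lists were higher than other genes by camera (adjusted p = 4.7e-05 for signalling, 5.7e-06 for transport, 2.8e-06 for phosphatases and 6.0e-08 for lipids). Each had adjusted p = 0.46 with an estimated correlation. After rescaling, 8, 8, 9 and 13 of their members rose, and camera again called all 4, with adjusted p = 0.17, 0.2, 0.17 and 0.17 at an estimated correlation.

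**Figure D2:**
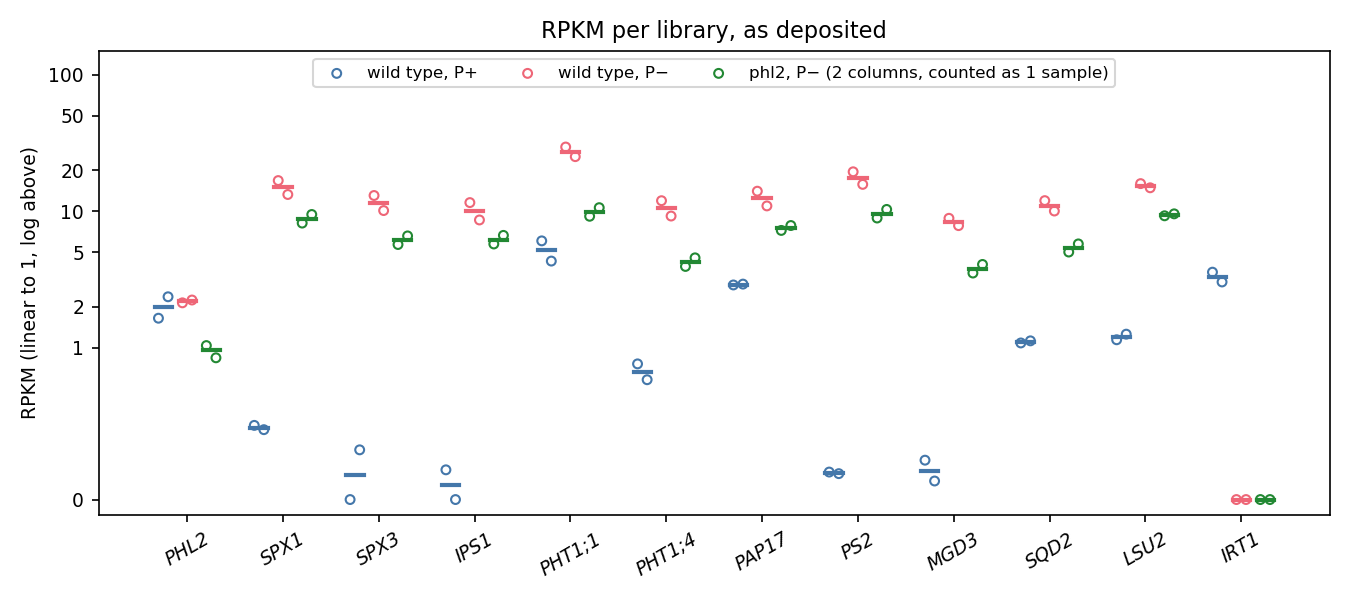
RPKM as deposited in each library (open circles; axis linear to 1 and logarithmic above) for PHL2 and 11 genes of the fixed lists, with horizontal bars at group means. The starvation genes are higher in both deficient wild-type libraries than in both with phosphate, the phl2 values (2 columns counted as 1 sample) lie between them, and IRT1 is listed at 0 in all deficient columns.

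Sulphur deficiency genes rose with them, in 10 of 11 cases as deposited and after rescaling, and in 10 adjusted over the list alone (camera adjusted p = 1.8e-06; adjusted p = 0.46 with an estimated correlation). LSU2 went from 1.20 ± 0.08 to 15.4 ± 0.77 RPKM and APR1, an enzyme of sulphate reduction, from 1.62 ± 0.61 to 14.8 ± 2.55. Glucosinolate synthesis genes rose in 12 of 14 cases, also adjusted over the list alone (camera adjusted p = 4.7e-05; adjusted p = 0.46 with an estimated correlation). MAM1, an enzyme of methionine chain elongation, changed by 3.01 ± 0.15, from 0.39 ± 0.03 to 10.2 ± 1.02 RPKM. BCAT4 went from 0.26 ± 0.04 to 9.73 ± 1.21, and 21.2% of its exons lie opposite to another gene's. After rescaling, 8 of the 14 rose and 1 fell.

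Root hair genes rose in 14 of 15 cases, 14 adjusted over the list alone and 11 after rescaling (camera adjusted p = 3.8e-05; adjusted p = 0.51 with an estimated correlation). PRP3, a root hair wall protein, went from 1.76 ± 0.07 to 8.32 ± 0.02 RPKM and LRX1 from 2.66 ± 0.01 to 9.77 ± 0.37. All 5 touch and early stress genes rose as deposited and adjusted over the list alone, and 4 after rescaling (camera adjusted p = 0.0015; adjusted p = 0.46 with an estimated correlation). TCH3, a calmodulin-like gene, went from 1.15 ± 0.41 to 8.83 ± 0.60 RPKM, with 20.2% of its exons opposite to another gene's.

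Iron deficiency genes went both ways. IRT1, the main iron importer of the root, was at 3.31 ± 0.39 RPKM with phosphate and listed at 0 in both deficient libraries (adjusted p = 1.0e-04). The ferric reductase gene FRO2 fell from 2.93 ± 0.09 to 0.12 ± 0.11 (-1.82 ± 0.16). F6'H1, which makes coumarin precursors, rose from 1.56 ± 0.01 to 4.04 ± 0.63. Of 12 genes, 2 rose and 3 fell, or 2 and 4 adjusted over the list alone, and 1 and 6 after rescaling (camera adjusted p = 1.6e-05; adjusted p = 0.46 with an estimated correlation). Markers of shoot photosynthesis were lower by camera (adjusted p = 9.7e-06; adjusted p = 0.46 with an estimated correlation), with 4 of 14 lower as deposited and adjusted over the list alone, and 7 after rescaling. PSBR fell from 6.63 ± 1.24 to 3.33 ± 0.19 RPKM and RCA, the Rubisco activase, from 3.40 ± 0.04 to 1.71 ± 0.10. Xylem and secondary wall genes were also lower by camera (adjusted p = 5.2e-04; adjusted p = 0.46 with an estimated correlation). Of 6 members, 0 were called as deposited and 5 were lower after rescaling, LAC4 by -0.76.

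The other lists were not called by camera. Nitrogen genes rose in 8 of 16 cases (adjusted p = 0.079), led by the nitrate reductase gene NIA2 (2.39 ± 0.22 to 12.9 ± 0.57 RPKM). Cell cycle and root meristem genes rose in 4 of 8 (adjusted p = 0.24) and hypoxia genes in 2 of 6 (adjusted p = 0.26). Endodermis and suberin genes rose in 3 of 9 (adjusted p = 0.85), jasmonate genes in 3 of 7 (adjusted p = 0.88) and iron storage genes in 2 of 4 (adjusted p = 0.36). After rescaling, 6, 1, 1, 0, 2 and 1 of these were higher, and 3 endodermis, 2 jasmonate and 1 nitrogen genes were lower. Adjusted over the list alone, as deposited, 8, 4, 4, 4, 3 and 2 were higher. Of the genes lower after rescaling, ESB1, KCS2 and MYC2 have 84.3%, 63.6% and 98.5% of their exons opposite to another gene's. Loci covered to at least 0.9 by opposite coding exons shifted by -0.042 in deficiency, against 0.381 for genes with no opposite-strand exon. Rescaling may thus have lowered such genes. The list of root apex aluminium and phosphate genes had 2 of 4 higher (adjusted p = 0.13), with the malate channel ALMT1 going from 0.31 ± 0.43 to 5.14 ± 0.21 RPKM. Anthocyanin and flavonoid genes had 1 higher and 2 lower of 6 (adjusted p = 0.07), chalcone synthase (CHS) falling from 7.47 ± 0.32 to 3.81 ± 0.76. Of the heat shock genes 1 of 3 was lower (adjusted p = 0.21). Of 4 phloem genes 0 were called (adjusted p = 0.85), and of 3 PHR-family genes 0 (adjusted p = 0.99). Adjusted over the list alone, the root apex list had 3 higher, the anthocyanin list 3 higher and 3 lower, the heat shock list 1 lower, and the phloem and PHR-family lists 0.

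Over all genes, 3210 were higher and 510 lower in deficiency as deposited, so that 86.3% of calls were higher. After rescaling, 929 were higher and 1342 lower, and 40.9% of calls were higher. With a change of at least 2-fold, 608 and 127 genes passed as deposited, and 284 and 316 after rescaling. The number higher as deposited was 1189, 635 and 1057 without replicate 2, 3 or 4, and the number lower was then 300, 187 and 208. Among genes named for size, a pair of pseudogenes on chromosome 1 had the largest rises. AT1G67610 (25339036 to 25340241) and AT1G67645 (25355112 to 25356129) were listed at 0 with phosphate, at 35.0 ± 1.96 and 25.2 ± 0.57 RPKM without, and at 30.6 and 23.0 in phl2. AT5G20790 went from 0.14 ± 0.20 to 17.0 ± 1.53 RPKM and AT5G53050 from 0.56 ± 0.39 to 23.2 ± 0.54. The largest falls were in another pair of neighbouring pseudogenes, AT1G33817 (chromosome 1, 12274982 to 12276763), from 21.4 ± 0.36 to 0.14 ± 0.12 RPKM, and AT1G33813 (12273243 to 12274646), from 17.9 ± 1.48 to 0.20 ± 0.08. MLO3 fell from 15.0 ± 0.17 to 1.56 ± 0.25. Counts of pseudogenes are uncertain, since reads can be shared with related copies.

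Under deficiency, phl2 roots had lower values than wild type for most genes, and few single genes were called once the shift was removed. As deposited, 33 genes were higher and 2230 lower, and 1.5% of calls were higher. After rescaling, limma called 8 genes higher and 2 lower, 80% of calls higher, with 2167 genes at an unadjusted p under 0.05. Quantile normalization gave 11 and 5, and genes with no opposite-strand exon, rescaled, 2 and 0. The count of 2230 depended on single libraries and on the pseudocount: it was 4, 3 and 9 without replicate 3, 4 or 5, 4272 without replicate 6, and 30 with a pseudocount of 0.1. At an unadjusted p under 0.05 the counts fell less, from 5456 genes lower to 2428, 4021 and 4597 without replicate 3, 4 or 5, and to 5230 with a pseudocount of 0.1. The count of 33 was 60, 59, 11, 19 and 10 without replicate 1, 2, 3, 4 or 5. Leaving out replicate 5 or 6 is not a change of library, since these columns held equal reads in 81.0% of genes. It chiefly changes the scale of the phl2 values, by the ratio of 1.156 in the worth of 1 read. With both phl2 columns taken as replicates, the counts were 188 and 7448 as deposited and 1383 and 999 after rescaling.

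The clearest difference was at a stretch of chromosome 1 that holds HEI10 and MRD1 on opposite strands. HEI10, a meiotic crossover factor (AT1G53490, 19963267 to 19966952), was listed at 14.2 ± 0.47 and 12.6 ± 0.73 RPKM in wild type with and without phosphate and at 0.19 in phl2 (-3.52 ± 0.16, adjusted p = 1.5e-04; -3.13 ± 0.17 after rescaling, adjusted p = 0.0044). MRD1 (AT1G53480, 19963047 to 19964712) was at 5.34 ± 0.71 and 9.07 ± 0.99 and was listed at 0 in phl2 (adjusted p = 5.3e-04 as deposited and 0.015 after rescaling). The genes overlap (41.3% of the exons of HEI10 and 89.8% of those of MRD1 lie opposite to another gene) and the strand counted is not given, so the values do not settle which of them differs, and each may hold reads of the other. The 8 genes higher after rescaling were named after their values were seen. AT2G07766, AT2G07793, AT3G44704, AT3G10526, ATMG01160 and ATMG00420 were listed at 0 in wild type and at 1.62 to 3.73 RPKM in phl2. These 6 passed the filter only through the phl2 columns, which share reads. AT2G07766, AT2G07793 and AT3G44704, of 87, 87 and 156 bp, rest on about 5, 6 and 3 reads in replicate 5 and 2, 2 and 3 in replicate 6, and the other three had no length in the reference. The other two were ARFD1A (1.67 ± 0.14 in deficient wild type, 4.32 in phl2) and the plastid locus ATCG00390 (1.31 ± 0.08 and 4.0). The AT2G07 loci are nuclear and the ATMG loci mitochondrial, and AT2G07793 and ATMG00420 had the same values.

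Other named differences were called as deposited and not after rescaling. GSTF7, a glutathione transferase, was at 8.16 ± 1.42 in wild type and 2.19 in phl2 (-1.52 ± 0.21, adjusted p = 0.036; -0.93 and adjusted p = 0.14 rescaled). AT2G45135, next to SPX3 on chromosome 2, was at 6.43 ± 0.20 and 1.64, and AT5G05960 at 5.33 ± 1.23 and 0.82. Among called genes with at least 5 RPKM, the limit for naming by size, the largest rises in phl2 as deposited were those of AT2G11271 (64.6 ± 1.58 and 105.2 RPKM), AT5G23411 (28.0 ± 2.54 and 43.8), AT3G51238 (13.3 ± 0.41 and 19.8), AT2G32179 (4.0 ± 0.10 and 7.08) and AT1G07702 (15.9 ± 0.09 and 22.8). From 51.5% to 100% of their exons lie opposite to another gene's.

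Whether genes of phosphate transport, phosphatases and lipid remodelling were lower in phl2 by more than other genes depended on the test, and 0 single members were called over all genes after rescaling. PHT1;1 was at 9.92 in phl2 (-1.37 ± 0.20, adjusted p = 0.04; -0.68 ± 0.15 and adjusted p = 0.14 rescaled), PHT1;2 at 9.28 (-1.47 ± 0.22; -0.79 ± 0.16 rescaled) and PHT1;4 at 4.26 RPKM (-1.13 ± 0.21; -0.50 ± 0.15 rescaled). Of 10 transport genes, 7 were lower as deposited and 10 adjusted over the list alone, against 0 and 3 after rescaling. Of 14 phosphatases and nucleases, 11 were lower and 13 adjusted over the list alone, against 0 and 1 after rescaling. PAP22 was at 4.79 ± 0.14 in wild type and 1.29 in phl2 (-1.34 ± 0.21; -0.83 ± 0.17 rescaled). Of 17 lipid remodelling genes, 10 were lower and 15 adjusted over the list alone, against 0 and 0 after rescaling, and DGD2 was at 2.26 ± 0.45 and 0.67. Camera with its preset correlation called these 3 lists lower than other genes (adjusted p = 0.0051 each; 0.016 each after rescaling). The calls were lost with an estimated correlation (adjusted p = 0.88 each; 0.53 each after rescaling), among genes with no opposite-strand exon (adjusted p = 0.09, 0.1 and 0.09) and with a minimum of 5 RPKM. By fry, which does not compare with other genes, adjusted p was 0.056 each.

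Phosphate signalling genes were not called by camera. Their median was -0.594 as deposited, against -0.478 over all tested genes, and -0.022 after rescaling, against -0.009. Of 12, 4 were lower as deposited, 11 adjusted over the list alone, and 0 by either count after rescaling. SPX1 was at 8.84 RPKM in phl2 (-0.70 ± 0.20 as deposited, adjusted p = 0.046; -0.02 ± 0.15 rescaled, adjusted p = 0.96). AT4 was at 16.1 RPKM, and its difference was -0.57 ± 0.17 as deposited and 0.13 ± 0.19 rescaled. IPS1 was at 6.22 RPKM (-0.61 ± 0.23, adjusted p = 0.074; 0.04 rescaled).

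Of the other lists, camera also called 4 lower in phl2, all of them lost after rescaling. These were nitrogen genes (10 of 16 lower, adjusted p = 0.0076, and 0.075 rescaled), glucosinolate synthesis (9 of 14, adjusted p = 0.0051, and 0.11 rescaled), sulphur deficiency (7 of 11, adjusted p = 0.045, and 0.19 rescaled) and endodermis and suberin genes (4 of 9, adjusted p = 0.045, and 0.075 rescaled). Each had adjusted p = 0.88 with an estimated correlation. In this order, their medians were -0.752, -0.685, -0.792 and -0.716 as deposited, against -0.478 over all tested genes. After rescaling they were -0.196, -0.163, -0.236 and -0.282, against -0.009, so a lost call does not show that the difference went away. Adjusted over the list alone, 14, 13, 9 and 9 members of these lists were lower as deposited. After rescaling the counts were 0, 0, 1 and 0, with 1 sulphur gene higher. SDI1, a sulphur-deficiency gene, was at 2.62 ± 0.45 in wild type and 0.53 in phl2, and CASP1, of the Casparian strip, at 2.35 ± 0.14 and 0.69. The remaining lists, with no call by camera, had 4 of 12 iron deficiency genes lower, 5 of 14 shoot photosynthesis genes, 3 of 6 anthocyanin genes, 2 of 15 root hair genes and 1 each of the jasmonate, phloem, touch and root apex lists. In iron storage, xylem, cell cycle, heat shock, hypoxia and PHR-family lists 0 members were called as deposited. Adjusted over the list alone, the counts lower were 5, 6, 3 and 2 for the iron deficiency, photosynthesis, anthocyanin and root hair lists, 1 for jasmonate, and 3 each for phloem, touch and root apex genes. They were 1 each for iron storage and heat shock, 0 for the cell cycle, and 3 each for xylem, hypoxia and PHR-family genes. These counts are as deposited. After rescaling they were 2 for photosynthesis, 1 for touch genes and 0 for the rest of these lists. After rescaling, the median of the photosynthesis list was 0.04 and its mean -0.17. RBCS1A, of the Rubisco small subunit, was at 1.75 ± 0.69 in wild type and 0.16 in phl2.

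How much of the starvation response phl2 held depended on the scale. Of the 608 genes induced at least 2-fold as deposited, 282 (46.4%) were called lower in phl2 and 0 higher, with a median log2 difference of -0.68. The median gene held 50% of the wild-type response (quartiles 33.5% and 67.8%). This share depended on the definition of induced genes: it was 19.4% with no fold minimum and 67.9% with at least 4-fold. The 282 became 498, 2, 1 and 4 without replicate 1, 3, 4 or 5, while the median difference stayed at -0.676, -0.627, -0.792 and -0.615, and 261, 493 and 419 genes were lower at an unadjusted p under 0.05 without replicate 3, 4 or 5. Of the 284 genes induced after rescaling, limma called 0 lower in phl2, with 74 lower and 21 higher at an unadjusted p under 0.05. Their median difference was -0.19 and the median gene held 87.1% of the response (quartiles 68.2% and 106%). With both phl2 columns as replicates, 506 of 612 induced genes (82.7%) were lower as deposited, and 77 of 275 (28%) after rescaling, where 17 were higher. For the genes repressed at least 2-fold, 4 of 127 were higher in phl2 as deposited and 5 lower still, with a median difference of 0.002 and 99.8% of the response held by the median gene. After rescaling, 1 of 316 was higher and 0 lower, with a median difference of 0.31 and 77.5% of the response held. With both phl2 columns as replicates, 28 of 128 were higher as deposited and 107 of 311 after rescaling. The 4 higher as deposited became 15, 11, 0, 0, 0 and 7 without replicates 1 to 6 in turn.

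These contrasts share the deficient wild-type libraries, which alone lowers genes selected as induced. In 50 simulations of an unchanged mutant against those libraries, the median difference of induced genes averaged -0.05 as deposited and -0.03 after rescaling (range -0.051 to -0.002), and at most 0.4% and 0.3% of them were called lower. The simulated group means were the observed ones, which already hold error of those libraries, so the simulated median and share may be too small in size. The simulated mutant had no library-wide shift. As deposited, the observed median and share thus depart from the simulated ones through that shift as well. The covariance of the 2 contrasts across genes was -0.07 as deposited and -0.06 after rescaling, against simulated covariances of -0.02 and -0.01. Genes raised by deficiency and lower in phl2 numbered 1173 as deposited, where independent lists of those sizes would share 624.5. Part of the excess may come from the shared libraries. The library-wide shift raises most genes in deficiency and lowers most in phl2, so independent lists are no fair baseline. After rescaling, 2 genes in all were lower in phl2. Induced genes were also taken from 1 deficient library, with phl2 set against the other. This removes error of single libraries that is independent from gene to gene. It does not remove a deviation that a library shares across these genes, or one common to both. The median difference was then -0.593 and -0.707 as deposited, and -0.18 and -0.187 after rescaling. As deposited, 95.8% and 92.8% of the genes were lower, little above the 91.2% of all tested genes in the full fit, and after rescaling 69.3% and 62.5%. As deposited, of 712 genes 0 were called lower and 0 higher, and of 473 genes 1 lower and 7 higher, each comparison having 1 library a side.

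Against wild type with phosphate, deficient phl2 roots had 291 genes higher and 598 lower as deposited (32.7% of calls higher), and 594 and 590 after rescaling (50.2%). The total of 889 became 450, 508 and 503 without replicate 1, 3 or 4. SPX1, PS2, PECP1 and SPX3 were again higher (adjusted p = 3.1e-04, 1.7e-04, 2.0e-04 and 9.2e-04), as were the pseudogenes AT1G67610 and AT1G67645 (adjusted p = 8.4e-06 and 9.4e-06), and AT1G33817 and AT1G33813 were lower (adjusted p = 4.3e-05 for both).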

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

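As reported, limma called 3210 genes higher and 510 lower in deficiency, 33 higher and 2230 lower in phl2, and 889 between phl2 and wild type with phosphate, with 282 of 608 induced genes lower and 4 of 127 repressed genes higher in phl2. The fit with both phl2 columns as replicates had been planned, and became an alternative once the columns were seen to share reads. The main fit on their mean was chosen after seeing the data. So were the fit on genes with no opposite-strand exon and the rescaled fit with separate libraries. Variances without a trend left all 9 counts within 1.5 times of these. Fits to the libraries of the compared groups alone gave 62 genes higher in phl2 and 590 for phl2 against wild type with phosphate, with the other 3 contrast counts within 1.5 times. With no filter on low values, 221 genes were higher and 57 lower in deficiency, 0 were higher and 0 lower in phl2, and 2 differed between phl2 and wild type with phosphate. Of 198 induced genes 0 were lower in phl2, and of 45 repressed genes 0 were higher. Under a minimum of 5 RPKM, 828 genes were higher and 241 lower in deficiency, 9 were higher and 829 lower in phl2, and 514 differed between phl2 and wild type with phosphate. Of 210 induced genes 131 were lower in phl2, and of 42 repressed genes 3 were higher. For a pseudocount of 0.1, 2557 genes were higher and 441 lower in deficiency, 7 were higher and 30 lower in phl2, and 888 differed between phl2 and wild type with phosphate. Of 1630 induced genes 6 were lower in phl2, and of 257 repressed genes 2 were higher. For a pseudocount of 5, 3396 genes were higher and 535 lower in deficiency, 40 were higher and 2137 lower in phl2, and 731 differed between phl2 and wild type with phosphate. Of 80 induced genes 51 were lower in phl2, and of 11 repressed genes 0 were higher. After rescaling by the median of ratios, 929 genes were higher and 1342 lower in deficiency, 8 were higher and 2 lower in phl2, and 1184 differed between phl2 and wild type with phosphate. Of 284 induced genes 0 were lower in phl2, and of 316 repressed genes 1 were higher. After quantile normalization, 1086 genes were higher and 1193 lower in deficiency, 11 were higher and 5 lower in phl2, and 1148 differed between phl2 and wild type with phosphate. Of 295 induced genes 1 were lower in phl2, and of 290 repressed genes 2 were higher. At an adjusted p under 0.01, 997 genes were higher and 205 lower in deficiency, 6 were higher and 2 lower in phl2, and 262 differed between phl2 and wild type with phosphate. Of 584 induced genes 0 were lower in phl2, and of 110 repressed genes 0 were higher. With 2-fold demanded of every call, 608 genes were higher and 127 lower in deficiency, 17 were higher and 320 lower in phl2, and 511 differed between phl2 and wild type with phosphate. Of 608 induced genes 93 were lower in phl2, and of 127 repressed genes 3 were higher. Under robust variances, 3728 genes were higher and 567 lower in deficiency, 47 were higher and 3697 lower in phl2, and 1226 differed between phl2 and wild type with phosphate. Of 602 induced genes 378 were lower in phl2, and of 126 repressed genes 7 were higher. Taking both phl2 columns as replicates, 5030 genes were higher and 743 lower in deficiency, 188 were higher and 7448 lower in phl2, and 3071 differed between phl2 and wild type with phosphate. Of 612 induced genes 506 were lower in phl2, and of 128 repressed genes 28 were higher. Among genes with no opposite-strand exon, rescaled, 659 genes were higher and 881 lower in deficiency, 2 were higher and 0 lower in phl2, and 985 differed between phl2 and wild type with phosphate. Of 214 induced genes 0 were lower in phl2, and of 239 repressed genes 0 were higher. Without a filter, 6154 genes were lower and 422 higher in phl2 at an unadjusted p under 0.05, and 488 and 749 among rescaled genes with no opposite-strand exon. With no fold minimum, 1173 of 3210 induced genes were lower and 8 of 510 repressed genes higher in phl2, and with at least 4-fold, 46 of 80 and 1 of 11. With induced genes from replicate 3 and phl2 against replicate 4, 0 genes were lower (328 at an unadjusted p under 0.05). The other way round, 1 was lower (275 unadjusted) and 7 were higher, and of repressed genes 0 were higher both ways. The median difference stayed at -0.593 and -0.707. After rescaling, these ways gave 225 and 216 induced genes, 0 and 0 of them lower in phl2, and 243 and 189 repressed genes, 0 and 0 higher. Leaving out 1 library at a time (replicates 1 to 6; where it left a group with 1 sample, that sample was assumed to vary like the others) gave 635 to 3293 genes higher and 187 to 510 lower in deficiency, and 10 to 60 higher and 3 to 4272 lower in phl2. The range for phl2 against wild type with phosphate was 450 to 999, for induced genes 486 to 853 with 1 to 498 of them lower in phl2, and for repressed genes 127 to 145 with 0 to 15 higher. Stricter thresholds and filters call fewer genes by construction, a larger pseudocount shrinks fold changes, and rescaling removes the library-wide shift. Leaving out replicate 5 or 6 chiefly changes the scale of the phl2 values, since these columns share most reads. The cause of the other changes was not tested. Camera called 11 lists in deficiency and 7 in phl2. With an estimated correlation it called 0 in both, and fry 16 and 0. After rescaling it called 11 and 3, with a minimum of 5 RPKM 7 and 0, with a pseudocount of 0.1 11 and 6, and on genes with no opposite-strand exon 11 and 0. The PHR-family list, not called by camera (adjusted p = 0.99), was called higher by fry (adjusted p = 0.018), which does not compare it with other genes. Of 87 named genes called in deficiency, 73 stayed called after rescaling with 0 changes of sign, and 48 with no filter. Of 71 called in phl2, 2 stayed called after rescaling and 3 changed sign: AT4 (0.13), C4H (0.05) and ACT2 (0.06). On genes with no opposite-strand exon, 5 changed sign in phl2, SPX1 (0.05), AT4 (0.19), C4H (0.11), PAL1 (0.05) and ACT2 (0.13), and PAL1 did in deficiency (-0.03). All of these had lost their call. Whether the list members below the filter were silent in these roots or too shallow to be seen was not tested. No paired analysis was possible because no replicate number occurs in more than 1 group.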

Other observations

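Of the tests below, those on the shift by overlap, on starvation genes from separate libraries after rescaling and on repressed genes against random lists were chosen after the result was seen. The random-list test of induced genes was written before its result, on a set of genes chosen after the data were seen.

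Loci that lie antisense to coding genes held the highest values. Of the 100 genes with the highest mean RPKM, 48 had over 0.5 of their exons opposite to coding exons, against 1.88% of all annotated genes, and non-coding loci covered to at least 0.9 by opposite coding exons had a median of 12 RPKM (n = 48) against 0.12 for non-coding loci with no opposite-strand exon (n = 152). Among coding genes the contrast was much weaker, with a median of 0.93 RPKM for those covered as far (n = 215) and 0.40 for those with no opposite-strand exon. Counting on the strand opposite to each gene may be the source. The levels of tail-to-tail coding neighbours with overlapping exons went together across 611 pairs (Spearman rho 0.363). Those of 1800 neighbours without overlap did not (0.018), a difference of 0.345 that had been predicted for such counting. Reads of both strands entering each value would also make overlapping neighbours go together, so this test does not single out the opposite strand. The fold changes of locus and partner by deficiency gave a rho of 0.144. This fell short of the rho written beforehand for opposite-strand counting, and lay above the rho written against it. The fold changes in phl2, for which no limit had been written, gave a rho of 0.003. The prediction had not allowed for the partner's value itself counting the locus, so neither rho decides. Abundant natural antisense RNA counted on its own strand stays open for these loci: the locus was higher than its coding partner in 84.2% of 38 pairs, which had been taken to argue against such RNA, but abundant antisense RNA would put the locus higher as well. If the opposite strand was counted, genes with no opposite-strand neighbour rest on residual reads of their own transcripts. Overlapping genes such as HEI10 and MRD1 would then hold each other's reads. The 5.44% to 9.07% of reads that the table holds would go with this, but these shares rest on an approximate worth of 1 read.

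The median gene was lower in phl2 than in deficient wild type. Genes with no opposite-strand exon and a mean above 2 RPKM shifted by a median of -0.55 (3131 genes), and loci covered to at least 0.9 by opposite coding exons by -0.07 (118 loci), 12.6% of that shift. A share of each gene's own reads on the counted strand that differs between libraries may account for it, and deficiency in wild type showed the like with the other sign (0.38 and -0.04). Lower transcript levels of most genes in phl2 stay open. The difference of 0.481 (bootstrap range 0.423 to 0.519) would argue against them only if the covered loci count the transcripts of their coding partners, and antisense RNA of their own is not excluded.

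Starvation induced genes were lower in phl2 than in deficient wild type. The library-wide shift is argued against as the whole cause: after rescaling on genes with no opposite-strand exon, the 214 induced genes had a median difference of -0.141, and 10000 random lists matched on level ranged from -0.04 to 0.04 (95% of lists). A fall beyond the shift was not seen in induced genes alone. The 7 reference genes had a median of -0.793 as deposited. After rescaling over all tested genes it was -0.141, with 5 of 7 negative, against -0.191 for the 284 induced genes of that fit. Chance values of single wild-type libraries that are independent from gene to gene are also argued against as the whole cause. Induced genes were taken from 1 deficient library and phl2 was set against the other, rescaled. The median was -0.18 (bootstrap range -0.235 to -0.1) and -0.187 (-0.246 to -0.089), where such error would leave it near 0. With 1 library a side, these ranges do not measure error between libraries. A deviation that a library shares across starvation genes, or one common to both deficient libraries, is not removed by this and stays open. The test first written, on the share called lower, says nothing here because 0% were called. Repressed genes went the other way: the 239 with no opposite-strand exon had a median of 0.29 after rescaling, above the -0.001 to 0.075 of random lists, and 0.27 and 0.251 with separate libraries. The shift may still account for most of the difference of -0.68 as deposited, and since phl2 is 1 sample, a difference between root batches and a lower response of phl2 both stay open, the mutant itself being the biological explanation that the design names and these data leave untested.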
